A study of Homo sapiens with 14 samples.

How the data were processed

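Peripheral blood mononuclear cells (PBMC, the lymphocytes and monocytes of blood) of 7 human donors were profiled with 10x 5′ single-cell RNA sequencing in 14 libraries. Each donor gave 1 library labelled pre (untreated) and 1 library labelled post (immunotherapy, day 22 after a triple therapy). The deposited matrices hold raw UMI counts per gene and cell barcode, with no normalization. The deposited barcode and feature files hold other text, namely the barcodes and the 36601 gene identifiers, which were the same in every library. The authors used Cell Ranger 6.1.2 and the human genome build GRCh38 (hg38), per the submitters' processing notes, and the version of their gene annotation was not stated. Gene positions were taken by gene identifier from GENCODE annotation on the same build, and all 193 genes named by the rule given further on were found there.

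Groups followed the titles and the treatment labels, and the number in the title was taken as the donor. The deposited file names give the opposite time point to the labels in 6 of 7 donors and the same time point in 1 donor. Which of them is right could not be settled from the deposited data, so libraries are called labelled pre and labelled post throughout, and the grouping by file name was run as an alternative. The pairing comes from the series description, which calls the samples paired, and from the shared number in the titles. As a check, the deviations of libraries with the same number from their group means correlated across genes by 0.106 to 0.91 in the 7 pairs. In this check 8 of 14 libraries correlated best with their own number and the rest with another, genes of the HLA, immunoglobulin and T cell receptor loci being left out. The check therefore does not establish the pairing, which rests on the description and the titles. Of 91 pairs of libraries, 0 were equal within sampling noise.

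Total counts per library ranged from 12557279 to 35854112 UMIs over 2909 to 8643 barcodes. Barcodes were kept with at least 200 genes and at most 10% of UMIs from mitochondrially encoded genes. Doublets were scored per library with Scrublet in scanpy 1.11.5. Its automatic threshold called 0 to 98 barcodes per library, so the highest-scoring barcodes were removed up to the expected number, 0.8% per 1000 barcodes. After these steps 1901 to 5536 cells per library remained, with median depths of 2803.5 to 6680 UMIs per cell, and 48586 cells were clustered. XIST, Y-linked genes and the variable segments of immunoglobulin and T cell receptor genes, 725 of the 36601 genes, were left out of every gene table.

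Counts were scaled per cell and log-transformed, 2000 variable genes were reduced to 30 principal components, and donor offsets were removed with the Harmony algorithm, rewritten in Python 3.11.15 with numpy 2.4.6 and scikit-learn 1.9.0. Cells were clustered with the Leiden algorithm (igraph 0.11.9) on a graph of 20 neighbours at resolution 1, first over all cells and then over T and NK cells alone. A cluster took the name of a cell class when at least 3 of its 10 most enriched genes were markers of that class and no other class had as many. Otherwise it stayed unnamed. Cell classes carry the ending "-like" because no surface protein was measured.

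UMI counts were summed per library and class, and donors with at least 20 cells of the class in both libraries entered the fit. Genes passing the filterByExpr filter were tested with the edgeR 4.0.16 quasi-likelihood test (R 4.3.3) after TMM scaling, with the donor as a block, and p-values were adjusted by Benjamini-Hochberg (BH) with a threshold of 0.05. Differences are log2 of labelled post over labelled pre with their standard errors (SE). Whether the Treg-like response differed from that of CD4 T-like cells was tested with a class by time term, with each library as a block. Cell class shares were compared with an exact two-sided paired sign-flip permutation test over 128 sign patterns, whose smallest possible p is 0.0156, and 95% Wilson intervals were computed for the share of each library. These intervals cover counting error only.

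The gene lists were tested with camera (limma 3.58.1) with a preset correlation between genes of 0.01, and p-values were adjusted by BH over all 136 tests of a list in a class. The lists were type I interferon response, interferon-gamma response, MHC class II presentation, proliferation, T cell co-inhibitory receptors and exhaustion, T cell activation and co-stimulation, cytotoxic effector, Treg suppressive molecules, Treg fragility and Th1-like, naive and stem-like T cell, T cell trafficking, TNF and NF-kB response, immediate early and stress, hypoxia and glycolysis, oxidative phosphorylation, VEGF ligands and receptors, TGF-beta response, monocyte suppressive and alarmin, and DNA damage and p53 response. Lists of platelet, erythroid, monocyte, B and plasma cell, and neutrophil transcripts stood for other cell types, and lists of cytosolic ribosomal proteins and mitochondrially encoded genes stood for RNA quality. Markers that name a class were dropped from the lists and from the named genes of that class, and a list was tested where at least 5 members remained.

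The genes named in the text follow a rule. Per class it takes up to 10 genes higher and up to 10 genes lower with the smallest p among those past the threshold with the same direction in all but 1 of the donors, leaving out unnamed loci and HLA genes, or the 5 with the smallest p where no gene passes. It adds 16 fixed receptors and regulators in Treg-like and CD8 T-like cells and 5 fixed genes in monocytes, among them VEGFA and HIF1A. It also adds up to 4 members of each list past its threshold. The part on genes past the threshold was also applied to the fit without replicate 1, an addition chosen after the data were seen, and the counts of named genes include it. The groups, markers, lists, tests, the rest of the naming rule and most alternatives were chosen before the data were examined.

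The alternatives were RLE size factors, DESeq2 1.42.0, no filter on low counts, no donor block, leaving out each donor in turn, time points from the file names, doublets kept, a mitochondrial limit of 20%, clustering without donor correction, and a minimum of 50 cells. For lists they were an estimated correlation, fry, no donor block and the fit without replicate 1. For shares they were the centred log-ratio, the logit, edgeR on cell counts and an unpaired permutation test. A minimum of 10 cells, cells thinned to 1000 UMIs, and the lists grouped by file name were added after the data were seen. The alternatives share donors and are not independent of each other.

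The fits were tested on simulated data, drawn from the fitted model of each class with 200 changed genes. In every simulation the changed genes were taken from those above the median of average expression, and genes were drawn independently of each other. The recovery therefore does not speak for genes of lower expression or for variation that genes share within a donor. At a difference of 1 log2 unit, edgeR recovered 97% to 100% of 100 changed genes in the 7 classes. At 0.5 log2 units it recovered 53% in Treg-like cells, 65% in classical monocyte-like cells and 99% in CD4 T-like cells, with 9 to 19 calls on unchanged genes per class. The class by time term recovered 79.5% of 200 genes changed by 1 log2 unit, with 10 calls on unchanged genes.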

Results

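The series is about anti-VEGF treatment (a block of vascular endothelial growth factor) and regulatory T cells (Tregs), and its donors received a triple therapy. It holds 14 libraries of blood mononuclear cells, 7 labelled pre and 7 labelled post, as pairs from 7 donors. The 7 libraries labelled pre held 12557279 to 30194848 UMIs and those labelled post 17784579 to 35854112 UMIs. The deposited file names contradict the time labels in 6 of 7 donors. Every direction given here is that of the labels, and 278 of the 290 gene and class pairs named by the rule pointed the other way when time was read from the file names. The libraries of replicate 3 stood apart in mitochondrial share, with medians per barcode of 22.7% labelled pre and 12.4% labelled post before filtering.

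The first comparison asked whether the mix of cell classes differed between the time points. Treg-like cells, named by FOXP3, IL2RA and CTLA4, made up 2.55% ± 1.43 (SD, n = 7) of kept cells in libraries labelled pre and 1.70% ± 0.689 (SD, n = 7) in those labelled post, a difference of -0.848 percentage points (-1.32 to -0.558 without single replicates). Their share of Treg-like plus CD4 T-like cells was 10.4% ± 6.20 (SD, n = 7) against 6.38% ± 2.16 (SD, n = 7), higher in 2 of 7 donors (exact sign-flip permutation test, two-sided p = 0.141). Clusters of T cells that stayed unnamed, 1 of them with 2095 cells, are not counted in this share. CD4 T-like cells differed by a mean of 2.88 percentage points (24.2% and 27.1%, higher in 3 of 7 donors, 0.874 to 4.29 without single replicates). NK-like cells differed by 2.68 (11.99% and 14.7%, 4 of 7 donors, 0.803 to 3.84) and CD8 T-like cells by 1.35 (16.5% and 17.9%, 5 of 7 donors, 0.673 to 2.35). The mean of B-like cells differed by -0.945 points while their share was higher in 6 of 7 donors, and by 1.32 without replicate 1. Classical monocyte-like cells differed by -0.0927 points (-2.74 to 2.25 without single replicates) and non-classical monocyte-like cells by -0.120 (-0.934 to 0.655), each higher in 3 of 7 donors. Antibody-secreting plasma cell-like cells had the smallest p, with 0.483% ± 0.374 against 0.223% ± 0.287 (SD, n = 7), higher in 1 of 7 donors (exact permutation test, p = 0.0469, BH adjusted p = 0.703 over 15 classes). None of the 15 named classes passed BH adjustment by the exact test. With time read from the file names, the Treg-like share of CD4 T-like cells differed by 5.71 points in the other direction (exact permutation p = 0.0312).

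**Figure D1:**
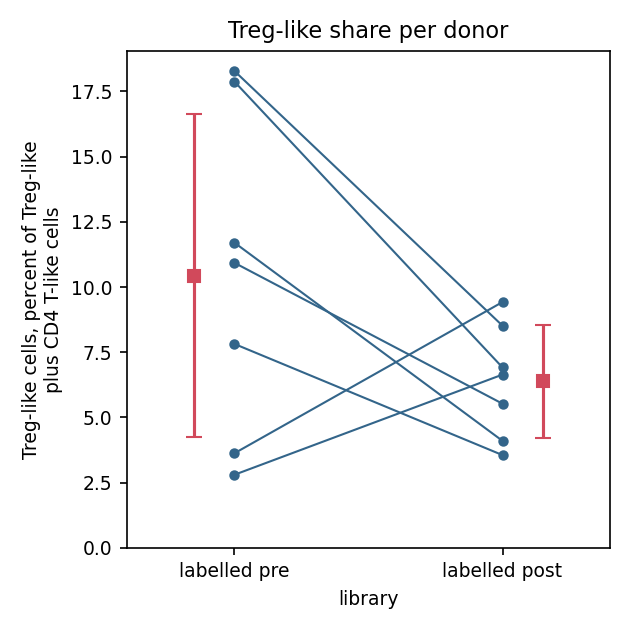
Treg-like cells as a percent of Treg-like plus CD4 T-like cells, for libraries labelled pre and labelled post. Points are libraries, lines join the 2 libraries of a donor, and squares with bars are the mean and SD of 7 libraries. The share was higher in the library labelled post in 2 of 7 donors.

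The second comparison asked which genes differed within Treg-like cells, in 6 donors with 526 cells labelled pre and 389 labelled post. Over all genes by edgeR, 4 of 21 type I interferon and 3 of 21 interferon-gamma list members fell. DESeq2 called only 1 lower gene in this class, so it did not make most of these interferon calls. IL7R, the receptor for the survival cytokine interleukin-7, rose, as did 4 of 32 members of the ribosomal protein list. The 3 lists passed by camera with the preset correlation and not with an estimated correlation (adjusted p = 0.0603, 0.0603 and 0.223). ISG15, an interferon-induced ubiquitin-like modifier, fell from a mean of 144 to 78.4 CPM (counts scaled to an equal library total), by 0.85 ± 0.17 on the log2 scale (SE, n = 6, edgeR adjusted p = 0.00303, higher in 1 of 6 donors). IL7R rose from 282 to 481 CPM, by 0.75 ± 0.13 (SE, n = 6), in 6 of 6 donors (edgeR adjusted p = 5.02e-04).

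Of 4870 genes tested in Treg-like cells, 25 changed by edgeR, 15 higher and 10 lower in libraries labelled post. DESeq2 gave another balance, 31 higher and 1 lower, and shared 11 of the 25 calls. At most 1 of the 10 lower calls was thus shared. Among the lower genes were GBP1, a guanylate-binding protein of the interferon-gamma response (-0.69 ± 0.15, SE, n = 6), and UBE2L6, the enzyme that attaches ISG15 (-0.73 ± 0.15). UCP2, a mitochondrial carrier, fell by 0.44 ± 0.11 on the log2 scale and C4orf48 by 0.80 ± 0.18. The higher genes included TCF7, a transcription factor of naive and memory T cells (0.54 ± 0.14, edgeR adjusted p = 0.0333, 6 of 6 donors). The long noncoding RNAs LINC00402 (1.13 ± 0.25) and PRKCQ-AS1 (0.57 ± 0.14) rose, as did MT-ATP8, a subunit of the mitochondrial ATP synthase (0.51 ± 0.10). IL7R (ENSG00000168685), a protein-coding gene, lies on chromosome 5 from 35852695 to 35879603 of GRCh38. The fixed receptors and regulators named next did not pass. TNFRSF4 (OX40, a co-stimulatory receptor) differed by -0.49 ± 0.17 (edgeR adjusted p = 0.202, higher in 2 of 6 donors) and the chemokine receptor CXCR3 by -0.64 ± 0.24 (higher in 1 of 6 donors). HIF1A differed by -0.41 ± 0.22, TNFRSF18 by -0.36 ± 0.22, ICOS by -0.25 ± 0.22 and ENTPD1 by -0.24 ± 0.32 (SE, n = 6). A minimum of 10 cells added replicate 1 and gave a count of 4. The count was 0 without the donor block and 0 with cells thinned to 1000 UMIs. It was 58, 8, 6, 9 and 4 without replicates 2, 3, 4, 6 and 7. It was 56 with a mitochondrial limit of 20%, 15 without the filter on low counts, and 25 in the other direction when time was read from the file names. Neither this fit nor that of non-classical monocyte-like cells holds replicate 1, which had 12 and 17 of these cells labelled pre. The other classes tested hold it, with 0 genes past the threshold, and had 5 to 60 without it. Counts of genes are therefore not compared between classes on the same donors.

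By gene list, 18 of the 21 interferon-gamma response members measured in Treg-like cells were lower, 3 of them changed over all genes and 12 adjusted over the list alone. The median log2 difference was -0.35, with a lower donor median in 6 of 6 donors (camera adjusted p = 3.37e-16). The type I interferon list, with ISG15, EPSTI1, LY6E and XAF1, had 4 of 21 members lower over all genes and 5 adjusted over the list alone (median -0.31, camera adjusted p = 7.25e-07). All 8 members of the Treg fragility and Th1-like list were lower, 1 over all genes and 2 adjusted over the list alone (median -0.42, camera adjusted p = 3.50e-06). In the naive and stem-like list, 2 of 12 members rose over all genes (IL7R and TCF7) and 5 adjusted over the list alone, with LEF1 at 0.38 ± 0.11 (median 0.31, camera adjusted p = 2.25e-06). The donor medians of the last 3 lists had the direction of the test in 6 of 6 donors, and each of these 4 lists had adjusted p = 0.0603 with an estimated correlation. All 32 members of the fixed ribosomal protein list were higher, 4 over all genes (RPL39, RPL34, RPS12 and RPS29) and 27 adjusted over the list alone. Ribosomal protein genes outside the list are not in these counts. Their median was 0.31, in 6 of 6 donors (adjusted p = 0.223 with an estimated correlation). All 13 mitochondrially encoded genes were higher, 1 over all genes and 7 adjusted over the list alone (median 0.24, 5 of 6 donors, adjusted p = 0.284 with an estimated correlation). The mean mitochondrial share of the Treg-like cells differed by 0.360 ± 0.358 percentage points (SE, n = 6). MHC class II genes were lower in 9 of 9 members, 1 over all genes (HLA-DRA at -0.60 ± 0.15) and 3 adjusted over the list alone. Their donor median was lower in 3 of 6 donors (median -0.22, adjusted p = 0.330 with an estimated correlation). The T cell activation list had 10 of 13 members lower, 1 over all genes (HLA-DRA again) and 2 adjusted over the list alone (median -0.25, adjusted p = 0.419 with an estimated correlation).

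The third comparison asked whether the response of Treg-like cells differed from that of CD4 T-like cells of the same libraries. The genes with the smallest p were CXCR3, with a difference of responses of -0.93 ± 0.21 log2 units (SE, n = 6), C4orf48 (-0.77 ± 0.18), ISG15 (-0.71 ± 0.18), UCP2 (-0.48 ± 0.12) and IL7R (0.54 ± 0.13), and none passed (smallest edgeR adjusted p = 0.147). Of 9186 genes, 0 passed by edgeR and 0 by DESeq2, with 549 and 356 at an unadjusted p under 0.05. The count was 1 without replicate 3 and 3 without the filter on low counts.

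Non-classical monocyte-like cells, the patrolling monocytes with FCGR3A, had 442 cells labelled pre and 416 labelled post in 4 donors. FCGR1A, the high-affinity IgG receptor induced by interferon-gamma, fell from 42.0 to 6.42 CPM, a log2 difference of -2.49 ± 0.27 (SE, n = 4), and was higher in 0 of 4 donors (edgeR adjusted p = 6.08e-06). FCGR1A (ENSG00000150337) lies on chromosome 1 from 149782671 to 149791675. GBP4 fell by 0.92 ± 0.12 on the log2 scale and SLAMF7, an activating receptor, fell by 1.72 ± 0.26 (SE, n = 4). CX3CR1, the fractalkine receptor of patrolling monocytes, fell by 0.63 ± 0.10, and the p53 target CDKN1A fell by 0.90 ± 0.15. CEBPD, a transcription factor of myeloid cells, rose by 0.67 ± 0.10 (edgeR adjusted p = 8.29e-04, 4 of 4 donors), and G0S2, an inhibitor of fat breakdown, rose by 1.21 ± 0.20.

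Of 6869 genes in non-classical monocyte-like cells, 56 changed by edgeR, 9 higher and 47 lower. This fit does not hold replicates 1, 5 and 7, which had under 20 of these cells in at least 1 library. All 24 interferon-gamma members were lower, 9 over all genes and 21 adjusted over the list alone (median -0.74, 3 of 4 donors, adjusted p = 0.215 with an estimated correlation). All 26 type I members were lower, 8 over all genes and 14 adjusted over the list alone, among them IFITM1 (-0.56 ± 0.09). The median was -0.43 (3 of 4 donors, adjusted p = 0.239 with an estimated correlation). All 12 MHC class II members were lower, 2 over all genes (HLA-DPB1 and HLA-DQB1) and 8 adjusted over the list alone. The median was -0.28 (3 of 4 donors, adjusted p = 0.237 with an estimated correlation). Transcripts of cytotoxic lymphocytes were higher, with GNLY at 1.59 ± 0.25 and CCL5 at 1.09 ± 0.23, 2 of 5 members over all genes and 2 adjusted over the list alone. NKG7 was at 1.38 ± 0.55 (median 1.38, 4 of 4 donors, adjusted p = 0.215 with an estimated correlation). RNA carried over from NK and T cells was not tested in the monocyte classes. The monocyte suppressive list was lower, with FCGR1A as 1 of 7 members past the threshold over all genes and 1 adjusted over the list alone. S100A9 was at -0.13 ± 0.10 (median -0.13, adjusted p = 0.431 with an estimated correlation). The immediate early list was lower, with ATF3 at -0.68 ± 0.18 and DUSP2 at 0.82 ± 0.24 (median -0.14, adjusted p = 0.704 with an estimated correlation). Of its 20 members, 1 higher and 1 lower passed adjusted over the list alone. HIF1A was at 0.24 ± 0.16 (edgeR adjusted p = 0.725, higher in 2 of 4 donors). The count was 17 by DESeq2, 0 without the donor block, 126 without the filter, 25, 187, 12 and 1 without replicates 2, 3, 4 and 6, and 56 in the other direction by file names. It was 24 with a mitochondrial limit of 20%, 94 without donor correction of the clusters and 14 with thinned cells. A minimum of 10 cells added replicate 1 and gave 6.

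Classical monocyte-like cells, the CD14 monocytes of blood, had no gene past the threshold in 6 donors, and interferon-gamma genes were lower as a list by camera (adjusted p = 0.190 with an estimated correlation). GBP5, a guanylate-binding protein that promotes inflammasome assembly, was at 54.0 CPM labelled pre and 14.0 labelled post. This is a log2 difference of -2.09 ± 0.31 (SE, n = 6, edgeR adjusted p = 0.0711, higher in 0 of 6 donors). ANKRD22 differed by -2.32 ± 0.42, WARS (WARS1 in the annotation), an interferon-induced tRNA synthetase, by -0.66 ± 0.12, PLAAT4 by -0.78 ± 0.14 and TRIM69 by -1.12 ± 0.22. DUSP1, a phosphatase of stress kinases, differed by 0.41 ± 0.08 (SE, n = 6, edgeR adjusted p = 0.0578 for each of these 5 genes). GBP5 (ENSG00000154451) lies on chromosome 1 from 89256189 to 89272860. Of 8372 genes, 0 passed by edgeR, 6 by DESeq2 (1 higher and 5 lower), and 444 had an unadjusted p under 0.05. Without replicate 1, 60 genes passed by edgeR, 11 higher and 49 lower. Among them were GBP2 at -1.19 ± 0.13 (edgeR adjusted p = 1.04e-06, higher in 0 of 5 donors), FCGR1A at -1.06 ± 0.13 and SERPING1, an inhibitor of complement, at -2.22 ± 0.32 (SE, n = 5). CXCR4 was at 0.63 ± 0.15 and the acute-phase protein gene PTX3 at 1.34 ± 0.32. The count was also 3, 1 and 22 without replicates 2, 3 and 5, 61 without the filter and 27 by file names.

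By list in classical monocyte-like cells, 22 of 24 interferon-gamma members were lower, 16 adjusted over the list alone, with PSMB10, an immunoproteasome subunit, at -0.47 ± 0.11. The median was -0.60, lower in 5 of 6 donors (adjusted p = 0.190 with an estimated correlation, and 0.0451 with it without replicate 1). The type I list had 2 of 29 members lower adjusted over the list alone, with SAMD9L at -0.84 ± 0.18 (median -0.17, adjusted p = 0.653 with an estimated correlation). MHC class II genes were lower (median -0.21, CIITA at -0.40 ± 0.13, adjusted p = 0.284 with an estimated correlation). Genes of oxidative phosphorylation were lower too (median -0.08, ATP5MC3 at -0.27 ± 0.09, adjusted p = 0.408 with an estimated correlation). The immediate early and stress list was higher, with 3 of 21 members adjusted over the list alone, DUSP1, IER2 at 0.34 ± 0.10 and BTG2 at 0.38 ± 0.11. Its median was 0.18 (5 of 6 donors, adjusted p = 0.284 with an estimated correlation). The TNF and NF-kB list was higher, with G0S2 at 1.54 ± 0.59 and PTGS2, the inducible prostaglandin synthase, at 0.62 ± 0.31 (median 0.18, adjusted p = 0.476 with an estimated correlation). The TGF-beta list was higher (median 0.13, SKI at 0.36 ± 0.24, adjusted p = 0.419 with an estimated correlation). So were the naive and stem-like list (median 0.20, FOXP1 at 0.24 ± 0.11, adjusted p = 0.239 with an estimated correlation) and the cytotoxic list (median 0.90, CST7 at 1.52 ± 0.49, adjusted p = 0.298 with an estimated correlation). Platelet transcripts were higher (median 0.18, ITGA2B at 0.45 ± 0.23, adjusted p = 0.603 with an estimated correlation). Their donor median was higher in 3 of 6 donors and its mean over donors was -0.11, the opposite sign to the test. Without replicate 1 the calls of the TNF and NF-kB list (median 0.056, camera adjusted p = 0.232) and the TGF-beta list (median 0.12, camera adjusted p = 0.110) ended. The medians of the type I and platelet lists were then -0.48 and 0.38. In these lists 0 members passed over all genes by edgeR (444 of 8372 genes at an unadjusted p under 0.05, and 6 by DESeq2), and only the 3 lists with a count given had members past the threshold adjusted over the list alone. The mix of clusters within the class was not held constant in these tests. VEGFA, the VEGF ligand itself, was at 17.45 and 17.56 CPM (0.13 ± 0.22, edgeR adjusted p = 1, higher in 3 of 6 donors, and -0.17 without replicate 6). HIF1A was at 0.39 ± 0.14 (edgeR adjusted p = 0.820, higher in 5 of 6 donors).

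CD8 T-like cells, the cytotoxic T cell class, had no gene past the threshold in 7 donors, and interferon-gamma genes were lower as a list by camera (adjusted p = 0.207 with an estimated correlation). GBP5 was at 240 and 190 CPM, -0.35 ± 0.07 (SE, n = 7, edgeR adjusted p = 0.406, higher in 0 of 7 donors). GBP1 was at -0.56 ± 0.12 and TAP1, the peptide transporter of MHC class I, at -0.33 ± 0.08. PHLDA1 was at 0.79 ± 0.19 and the growth factor gene AREG at 0.58 ± 0.14. Of the checkpoint and activation genes fixed for this class none passed (edgeR adjusted p = 1 for each). PDCD1 was at -0.12 ± 0.18, HAVCR2 at 0.19 ± 0.29, ICOS at -0.30 ± 0.15 and TNFRSF18 at 0.21 ± 0.32 (SE, n = 7). IFNG was at -0.27 ± 0.33 and CXCR3 at -0.30 ± 0.26. TBX21 (-0.05 ± 0.08) turned to 0.0048 and 0.010 without replicates 1 and 7. TNFRSF9 (-0.14 ± 0.25) turned to 0.049 without replicate 5, and HIF1A (0.02 ± 0.08) to -0.020 and -0.0054 without replicates 1 and 5.

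Of 9947 genes in CD8 T-like cells, 0 passed by edgeR and 0 by DESeq2, and 387 had an unadjusted p under 0.05. Without replicate 1, 17 passed by edgeR, 2 higher and 15 lower. Among them were ISG15 at -0.45 ± 0.08 (edgeR adjusted p = 0.00702, higher in 0 of 6 donors), IRF9 at -0.40 ± 0.07, IFI30 at -1.02 ± 0.18 and PHLDA1 at 0.90 ± 0.18 (SE, n = 6). The count was 15 by file names, 16 without the filter and 1 with thinned cells. In the interferon-gamma list 21 of 24 members were lower, 10 adjusted over the list alone (median -0.22, 6 of 7 donors, adjusted p = 0.207 with an estimated correlation). In MHC class II 11 of 12 members were lower, 1 adjusted over the list alone, with HLA-DRA at -0.61 ± 0.21 (median -0.25, 6 of 7 donors, adjusted p = 0.207 with an estimated correlation). The ribosomal list was higher (RPL39 at 0.09 ± 0.07, median 0.01, adjusted p = 0.837 with an estimated correlation), with a higher donor median in 3 of 7 donors. The ribosomal median was 0.030 without replicate 1. Mitochondrially encoded genes were higher (MT-ND4L at 0.13 ± 0.06, median 0.06, 5 of 7 donors, adjusted p = 0.431 with an estimated correlation). In these 4 lists 0 members passed over all genes by edgeR (387 of 9947 genes at an unadjusted p under 0.05, and 0 by DESeq2), and in the last 2 lists 0 passed adjusted over the list alone. The type I interferon list did not pass with all donors (median -0.03, camera adjusted p = 0.445). Without replicate 1 it was lower, 9 members adjusted over the list alone (median -0.15, camera adjusted p = 1.16e-11, and 0.0451 with an estimated correlation).

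NK-like cells, innate cytotoxic lymphocytes, had no gene past the threshold in 7 donors, with interferon-gamma genes lower and naive and stem-like genes higher as lists by camera (adjusted p = 0.0603 and 0.149 with an estimated correlation). IER3 was at 18.8 and 11.9 CPM, -0.71 ± 0.15 (SE, n = 7, edgeR adjusted p = 0.377, higher in 0 of 7 donors). STAT2, a transcription factor of type I interferon signalling, was at -0.39 ± 0.10, TRIM69 at -0.53 ± 0.13, LINC02384 at -0.37 ± 0.09 and TMEM123 at 0.30 ± 0.07. IL7R was at 81.1 and 151 CPM, 0.97 ± 0.24 (SE, n = 7, edgeR adjusted p = 0.606, higher in 6 of 7 donors). Of 9911 genes, 0 passed by edgeR and 0 by DESeq2, and 635 had an unadjusted p under 0.05. Without replicate 1, 60 passed by edgeR, 23 higher and 37 lower. Among them were IL7R at 1.16 ± 0.10 (edgeR adjusted p = 7.10e-05, higher in 6 of 6 donors), RPL34 at 0.28 ± 0.05, IRF9 at -0.41 ± 0.06 and CD74 at -0.30 ± 0.05 (SE, n = 6). NLRC5, the activator of MHC class I genes, was at -0.36 ± 0.07. The count was 45 by file names and 8 without the filter.

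In NK-like cells 20 of 23 interferon-gamma members were lower, 13 adjusted over the list alone (median -0.26, 6 of 7 donors, adjusted p = 0.0603 with an estimated correlation). In MHC class II 10 of 11 members were lower, 5 adjusted over the list alone, with HLA-DRB1 at -0.32 ± 0.08 (median -0.22, 6 of 7 donors, adjusted p = 0.0603 with an estimated correlation). The type I list was lower, with 2 of 32 members adjusted over the list alone and OAS1 at -0.47 ± 0.14 (median -0.12, or -0.23 without replicate 1, adjusted p = 0.387 with an estimated correlation). The cytotoxic list was lower, with FASLG at -0.28 ± 0.12 and GZMA at -0.18 ± 0.08 (median -0.14, adjusted p = 0.293 with an estimated correlation). All 13 naive and stem-like members were higher, 4 adjusted over the list alone, with LEF1 at 0.43 ± 0.12 and CD27 at 0.46 ± 0.17. Their median was 0.28, in 6 of 7 donors (adjusted p = 0.149 with an estimated correlation). All 32 ribosomal genes were higher, 26 adjusted over the list alone (RPL41 at 0.20 ± 0.06, median 0.14, adjusted p = 0.237 with an estimated correlation). All 13 mitochondrially encoded genes were higher (MT-ND3 at 0.21 ± 0.09, median 0.06, adjusted p = 0.470 with an estimated correlation). With all donors 0 members of these 7 lists passed over all genes by edgeR, as no gene of this class did. Of 9911 genes, 635 had an unadjusted p under 0.05 and 0 passed by DESeq2.

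CD4 T-like cells, the helper T cell class, had no gene past the threshold in 7 donors, with interferon-gamma genes lower and p53 response genes higher as lists by camera (adjusted p = 0.237 and 0.0603 with an estimated correlation). GBP2 was at 87.9 and 72.7 CPM, -0.29 ± 0.07 (SE, n = 7, edgeR adjusted p = 0.351, higher in 0 of 7 donors). The acetyltransferase gene KAT2B was at 0.32 ± 0.07, B3GNT9 at 0.57 ± 0.13, CST7 at 0.37 ± 0.08 and LINC01871 at 0.47 ± 0.11. Of 11423 genes, 0 passed by edgeR and 0 by DESeq2, and 405 had an unadjusted p under 0.05. Without replicate 1, 9 passed by edgeR, LINC01871 (0.58 ± 0.10) and MT-ATP8 (0.34 ± 0.06) higher and IRF1 (-0.42 ± 0.07), GBP2 (-0.32 ± 0.06), HAPLN3, PSME2, NXT1, PSMB9 and LGALS3BP lower. Each had the same direction in 6 of 6 donors (SE, n = 6, edgeR adjusted p of 0.0457 to 0.0498). The count was 2 without replicate 3 and 18 without the filter.

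By list in CD4 T-like cells, 21 of 24 interferon-gamma members were lower, 8 adjusted over the list alone, with IRF1, a transcription factor induced by interferon-gamma, at -0.36 ± 0.08. The median was -0.18, in 6 of 7 donors (adjusted p = 0.237 with an estimated correlation). The type I list was lower (PARP14 at -0.18 ± 0.07, median -0.07, adjusted p = 0.444 with an estimated correlation). Of 21 genes of the p53 response 20 were higher, with RPS27L at 0.14 ± 0.07 and the cell death gene BAX at 0.11 ± 0.06. Their median was 0.12, in 7 of 7 donors (adjusted p = 0.0603 with an estimated correlation). The cytotoxic list was higher (CCL5 at 0.33 ± 0.22, median 0.14, adjusted p = 0.284 with an estimated correlation), and so was trafficking (CCR10 at 0.35 ± 0.20, median 0.13, adjusted p = 0.388 with an estimated correlation). The Treg suppressive list was higher (LGALS1 at 0.46 ± 0.09, median 0.08, adjusted p = 0.293 with an estimated correlation). Oxidative phosphorylation (ATP5MG at 0.10 ± 0.06, median 0.03) and ribosomal genes (RPL39 at 0.12 ± 0.06, median 0.04) were higher, with adjusted p = 0.704 and 0.603 with an estimated correlation. With all donors 0 members of these lists passed over all genes by edgeR, as no gene of this class did. Of 11423 genes, 405 had an unadjusted p under 0.05 and 0 passed by DESeq2. Adjusted over the list alone, CST7 passed in the cytotoxic list and LGALS1 in the Treg suppressive list. Without replicate 1 the calls of the Treg suppressive list (median 0.053, camera adjusted p = 0.214) and of oxidative phosphorylation (median 0.013, camera adjusted p = 0.185) ended, and LGALS1 no longer passed over its list. The type I and cytotoxic medians were then -0.16 and 0.26. The mix of naive and memory clusters was not held constant in these tests.

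B-like cells had no gene past the threshold in 7 donors, with p53 response genes higher and interferon-gamma genes lower as lists by camera (adjusted p = 0.0603 and 0.284 with an estimated correlation). TP53INP1, a stress-induced p53 target, was at 67.3 and 96.5 CPM, 0.50 ± 0.11 (SE, n = 7, edgeR adjusted p = 0.356, higher in 7 of 7 donors). PSMB9, an immunoproteasome subunit, was at -0.32 ± 0.08, GLO1 at 0.49 ± 0.11, CAD, the first enzyme of pyrimidine synthesis, at -1.0 ± 0.24 and RPS19 at 0.17 ± 0.04. Of 8406 genes, 0 passed by edgeR and 0 by DESeq2, and 333 had an unadjusted p under 0.05. Without replicate 1, 5 passed by edgeR, RPS19 higher and 4 lower, among them GBP4 (-0.73 ± 0.13), PSMB9 (-0.35 ± 0.07) and B2M (-0.21 ± 0.04, SE, n = 6). The count was 2 without replicate 5, 4 by file names and 8 without the filter.

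By list in B-like cells, 14 of 15 members of the p53 response were higher, 2 adjusted over the list alone, with SESN1 at 0.41 ± 0.13 and the death receptor gene TNFRSF10B at 0.54 ± 0.21. The median was 0.24, in 7 of 7 donors (adjusted p = 0.0603 with an estimated correlation). Of 22 interferon-gamma members 21 were lower, 1 adjusted over the list alone (median -0.19, 5 of 7 donors, adjusted p = 0.284 with an estimated correlation). Oxidative phosphorylation was higher (ATP5MC1 at 0.29 ± 0.10, median 0.05, adjusted p = 0.419 with an estimated correlation), as were hypoxia and glycolysis (ANKRD37 at 0.60 ± 0.21, median 0.05, adjusted p = 0.293 with an estimated correlation). Immediate early genes were higher (DNAJB1 at 0.21 ± 0.11, median 0.13, adjusted p = 0.557 with an estimated correlation). Ribosomal proteins (RPL34 at 0.15 ± 0.04, median 0.06) and mitochondrially encoded genes (MT-ND4L at 0.10 ± 0.05, median 0.03) were higher, with adjusted p = 0.239 and 0.578 with an estimated correlation. Without replicate 1 the call of hypoxia and glycolysis ended (median 0.034, camera adjusted p = 0.103), and the immediate early and mitochondrially encoded medians were 0.083 and 0.0085. The type I interferon list did not pass with all donors (median -0.03, camera adjusted p = 0.360) and was lower without replicate 1 (median -0.14, camera adjusted p = 2.82e-07, and 0.255 with an estimated correlation). With all donors 0 members of these lists passed over all genes by edgeR, as no gene of this class did. Of 8406 genes, 333 had an unadjusted p under 0.05 and 0 passed by DESeq2.

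Across classes, the interferon-gamma list was lower in 7 of 7 classes, type I interferon and MHC class II in 5 each, and ribosomal proteins higher in 6 and mitochondrially encoded genes in 5. These are calls by camera with the preset correlation, and none of them held with an estimated correlation (smallest adjusted p = 0.0603). Without replicate 1, type I interferon was lower in 7 of 7 classes and MHC class II in 6 by camera with the preset correlation. In non-classical monocyte-like cells the ribosomal (median 0.13, adjusted p = 0.419 with an estimated correlation) and mitochondrially encoded lists (MT-ATP8 at 0.33 ± 0.10, median 0.13, adjusted p = 0.585 with an estimated correlation) were higher with 0 members adjusted over the list alone by edgeR. In all, 52 of 136 tests of a list in a class passed by camera, 29 higher and 23 lower, and 39 passed without the donor block. Without replicate 1, 57 passed, with 5 of the 52 calls ended and 10 others gained. With an estimated correlation 11 then passed, 4 of them in Treg-like cells, whose fit does not hold that replicate and whose values moved only through the adjustment over all tests. By file names 58 passed, and 50 of the 52 pointed the other way. Proliferation (7 classes tested), co-inhibitory receptors and exhaustion (3), monocyte transcripts (2) and B and plasma cell transcripts (1) passed in no class. VEGF ligands and receptors, erythroid and neutrophil transcripts had fewer than 5 members measured in every class and were not tested.

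**Figure D2:**
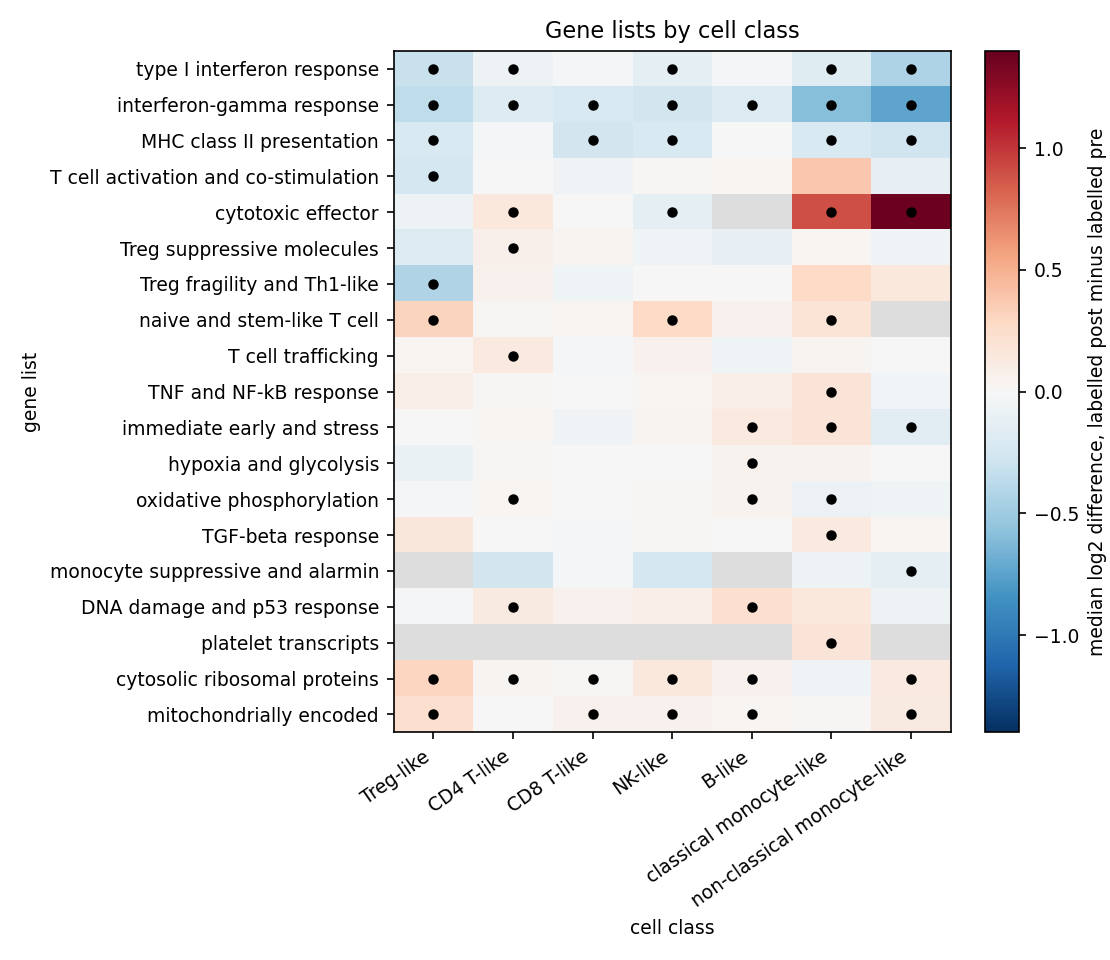
Median log2 difference (labelled post minus labelled pre) of each gene list in each cell class as colour, with grey for lists not tested there. Dots mark the 52 tests past the threshold by camera with the preset correlation, and the interferon-gamma list carries a dot in all 7 classes.

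**Figure D3:**
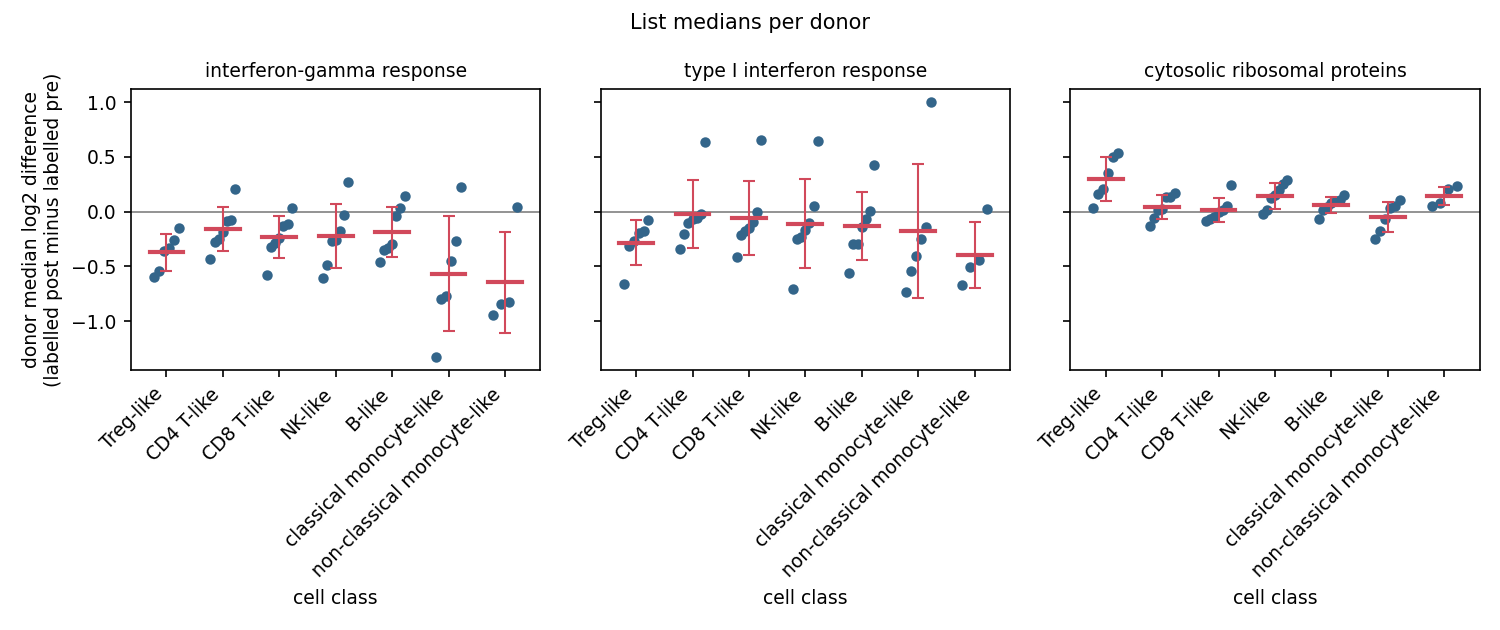
Donor medians of the log2 difference (labelled post minus labelled pre) for 3 lists in each class. Points are donors, and bars are the mean and SD over the donors of the class, 4 to 7 in number. The interferon-gamma median was below 0 in 6 of 6 donors in Treg-like cells and in 6 of 7 in NK-like cells.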

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

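The tests of exchanged time labels, of the mitochondrial share of the cells and of other splits of the donors were chosen only after the results were seen. A library stood far from the others of its group, by Dixon's criterion, in 15 of 114 groups of values tested, and chance alone gives about 1 in 20.

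Before filtering, the median mitochondrial share per barcode was 22.7% in 1 library labelled pre against 3.68% to 7.63% in the other 6, and 12.4% in 1 library labelled post against 3.45% to 5.63%. Among kept cells, 1 library labelled pre had a median depth of 2803.5 UMIs against 5060 to 6680. B-like cells made up 27.7% of 1 library labelled post (95% Wilson interval 26.3% to 29.2%) against 2.44% to 8.66% in the other 6. MAIT-like cells, T cells that recognise bacterial vitamin B2 metabolites, made up 6.87% of 1 library labelled post (95% Wilson interval 6.11% to 7.72%) against 0.221% to 2.96%. NK-like cells made up 26.1% of 1 library labelled pre (95% Wilson interval 24.5% to 27.8%) against 6.65% to 11.9%. Cycling-like cells made up 2.70% of 1 library labelled pre (95% Wilson interval 2.17% to 3.37%) against 0.460% to 1.34%. In 1 library labelled post each, erythroid-like cells were at 0.349% (95% Wilson interval 0.221% to 0.551%, the others at 0.135% or less), plasma cell-like cells at 0.836% (0.590% to 1.18%, the others at 0.313% or less) and plasmacytoid DC-like cells at 2.12% (1.77% to 2.54%, the others at 0.116% to 0.647%).

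Among the named genes in Treg-like cells, IL7R was at 310 CPM in 1 library labelled post against 477 to 560 CPM in the other 5. In 1 library labelled pre each, UBE2L6 was at 179 CPM against 215 to 230 CPM, UCP2 at 975 CPM against 433 to 611 CPM and XAF1 at 230 CPM against 97.9 to 142 CPM. SLAMF7 in non-classical monocyte-like cells was at 72.1 CPM in 1 library labelled pre against 32.7 to 38.1 CPM in the other 3.

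Interferon-gamma response genes were lower in libraries labelled post in all 7 classes by camera with the preset correlation, with list medians of -0.18 to -0.74, and the list passed in no class with an estimated correlation (adjusted p of 0.0603 to 0.284). Of the 5 classes whose fit holds replicate 1, leaving it out gave 0.0451 in CD8 T-like and classical monocyte-like cells and 0.0511 to 0.184 in the other 3. The values argue against the mitochondrial share of the cells, whose difference accounts for at most 0.012 log2 units in a class. This bound includes 2 standard errors of the difference in share. It leaves out the error of the change in the list per point of share, which was measured within libraries. In CD4 T-like, CD8 T-like, NK-like and B-like cells the values also argue against free RNA from monocytes. It supplies 0.251% of the UMIs of these genes, where their level was lower by 11.99% to 16.3%. Treg-like cells were not part of this test. Exchanged time labels stay open, since the list median of the 1 donor with matching file names had the opposite sign to the mean of the other donors in 5 of 5 classes, and 1 donor is too few to decide. The treatment itself may account for the pattern, but time and label cannot be told apart here, so its direction relative to treatment is open as well.

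In Treg-like cells labelled post, IL7R was higher by 0.75 ± 0.13 (SE) and ribosomal protein genes by a median of 0.31, a list that did not pass with an estimated correlation (adjusted p = 0.223). Conventional CD4 T-like cells mixed into the class would have to make up 13.9% of it to give the IL7R difference. Such a mixture would lower the 13 Treg markers, which also served to name the class, by a median of 0.20 log2 units. These markers had a median of 0.0081, above that of the mixture, with an SE of their mean over the 13 markers of 0.053. That error does not cover the spread between donors. The SE of single markers was 0.11 to 0.23, so the test does not settle the question. The members went both ways, from -0.37 to 0.23, with FOXP3 at -0.04 ± 0.11 and IL2RA at -0.08 ± 0.13, and TBC1D4 (-0.37 ± 0.15), CTLA4 (-0.29 ± 0.14) and DUSP4 (-0.21 ± 0.17) were as low as the mixture would make them or lower. The difference in mitochondrial share predicts -0.041 for the ribosomal list, the opposite sign. The depth of the cells stays open, since cells thinned to 1000 UMIs left IL7R at 0.53 ± 0.23 (SE) and ended every call, with a smaller difference and a larger error. An effect of treatment on these cells may also account for the pattern and was not separable from the time labels, which the file names contradict.

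Naive and stem-like genes were higher in NK-like cells labelled post by camera, with a mean donor median of 0.23, and the list did not pass with an estimated correlation (adjusted p = 0.149). In this class 0 genes passed by edgeR and 0 by DESeq2 with all donors, and 635 had an unadjusted p under 0.05. The mix of NK-like clusters stays open, since the list median within the largest cluster was 0.15 ± 0.055 (SE, 7 donors), between none of the difference and all of it. RNA from T cells stays open too, since subtracting CD4 T-like RNA left the mean IL7R difference at 0.70 ± 0.41 (SE) against 0.80 ± 0.25 before. A change of the NK cells themselves with treatment may account for the pattern and was not tested apart from these.

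Exchanging the 2 libraries within donors gave a check on chance for each count of genes. In Treg-like cells 1 of 32 such splits, the labels themselves, gave 25 genes or more, and the highest other split gave 12. For this count alone, in the fit with all 6 donors, the share of such splits is under 0.05. The share of 1 in 32 is the smallest this design can give. It was not adjusted over the counts of the other classes, and the check was chosen after the results were seen. The splits were not run under the settings that lowered the count, so chance is not excluded. In non-classical monocyte-like cells the 8 splits are too few for a share under 0.05, with 56 genes by the labels and 69 in the highest other split. For CD4 T-like, CD8 T-like, NK-like and B-like cells the labels gave 0 genes by edgeR, as few as or fewer than all 64 splits, with highest other counts of 5, 15, 90 and 4 (DESeq2 gave 0 in each, and 405, 387, 635 and 333 genes had an unadjusted p under 0.05). For classical monocyte-like cells (DESeq2 6, unadjusted 444) and the difference between Treg-like and CD4 T-like responses (DESeq2 0, unadjusted 549) edgeR also gave 0, as few as or fewer than all 32 splits, with highest other counts of 27 and 2. The split that follows the file names was the highest of 64 in CD8 T-like cells (15 genes) and of 32 in classical monocyte-like cells (27), and in NK-like cells it gave 45 genes, where 1 other split gave 90. The splits cannot tell 1 deviating donor from exchanged labels or from chance, and the cause of these counts was not tested. The counts by file names rest on 1 donor, the only one set against the others in that split, and the 3 classes share the same donors. The split by file names gave 4 genes in B-like cells, a count that 4 of the 64 splits reached, and 0 in CD4 T-like cells, as few as or fewer than any split.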

How the results depend on the processing

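Time points from the file names and the minimum of 50 cells were planned, while the minimum of 10 cells, thinned cells, and lists grouped by file name were chosen after the data were seen. The cause of each change was not tested, except that a higher or lower minimum of cells changes the donors in the fit. In Treg-like and non-classical monocyte-like cells the minimum of 10 cells added replicate 1 alone. The falls to 4 and 6 genes came with that donor. The counts of Treg-like genes (25) became 15 with no filter, 0 with no replicate block, 56 with a mitochondrial limit of 20%, 4 with a minimum of 10 cells, 0 thinned, and 4 to 58 without single replicates (58, 8, 6, 9 and 4 without replicates 2, 3, 4, 6 and 7). Of the 25, 11 were shared with DESeq2 and 24 with doublets kept. Non-classical monocyte-like genes (56) became 17 by DESeq2, 126 with no filter, 0 with no replicate block, 24 with a mitochondrial limit of 20%, 94 with no donor correction, 6 with a minimum of 10 cells, 14 thinned, and 1 to 187 without single replicates (25, 187, 12 and 1 without replicates 2, 3, 4 and 6). By file names both counts reversed, at 25 and 56, because every donor in those fits changes sides. Counts of 0 by edgeR became, with no filter, 18 in CD4 T-like, 16 in CD8 T-like, 8 in NK-like, 8 in B-like and 61 in classical monocyte-like cells, and 3 for the difference of responses. They ranged without single replicates from 0 to 9, 17, 60, 5 and 60 in the same 5 classes and to 1 for the difference of responses, the highest without replicate 1 except for the last (without replicate 3). By file names they were 15 in CD8 T-like, 45 in NK-like, 4 in B-like and 27 in classical monocyte-like cells. Classical monocyte-like genes were also 6 by DESeq2, 13 with doublets kept, 11 with a mitochondrial limit of 20%, 22 with a minimum of 50 cells, 4 with a minimum of 10, and 4 thinned, and CD8 T-like genes 1 thinned. Lists (52) became 0 with an estimated correlation, 2 by fry and 58, reversed, by file names. The donor block changed the calls of 44 named genes, all to no call without it, turned SPARC in classical monocyte-like cells from 0.26 to -0.0062, and moved no count other than those given by over 1.5 times. For the shares of the named classes no test passed BH in any setting. The file names reversed Treg-like (1.12 points), CD4 T-like (-3.35), CD8 T-like (-1.03), NK-like (-1.95) and non-classical monocyte-like (1.48), and the Treg-like share of CD4 T-like cells (5.71). This last share had a single test without BH, and by file names its exact permutation p was under 0.05. The B-like share turned to 0.281 by centred log-ratio and 0.0941 by edgeR, and non-classical monocyte-like to 0.191 by centred log-ratio. Without single replicates B-like ranged from -1.49 to 1.32, classical monocyte-like from -2.74 to 2.25 and non-classical monocyte-like from -0.934 to 0.655. Named genes that reversed without single replicates included TBX21 (-0.10 to 0.010), TNFRSF9 (-0.23 to 0.049) and HIF1A (-0.020 to 0.035) in CD8 T-like cells, VEGFA (-0.17 to 0.25) and SPARC (-0.078 to 0.42) in classical monocyte-like cells, and MSR1 (-0.47 to 0.034) in non-classical monocyte-like cells. In the 290 named values, DESeq2 ended 9 calls and added 5, and RLE size factors ended 1 and left 289 unchanged. The other 276 under DESeq2 hold values with no call by either tool. They also hold values to which DESeq2 gave no adjusted p, so they are not a count of calls kept. Of all calls, DESeq2 shared 11 of 25 in Treg-like cells and 12 of 56 in non-classical monocyte-like cells. Treg-like cells, 526 labelled pre and 389 labelled post, gave no call when thinned, and whether depth limits this fit stays open.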

Other observations

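The clusters described here matched no class and were chosen after their values were seen. A cluster of 168 T cells with FXYD2, GZMK, CD27, MYB and HAVCR2 among its most enriched genes had 132 cells in libraries labelled pre and 36 in those labelled post, and no library held more than 29.2% of it. Without the library that held the most of it, it had 83 and 36 cells. A cluster of 2095 T cells had GATA3, the master regulator of type 2 helper cells, and the skin-homing receptor gene CCR4 among its most enriched genes, with FOXP3 detected in 2.82% of the cells against 62.8% of Treg-like cells. It had 1169 cells labelled pre and 926 labelled post, and 865 and 926 without the library that held the most of it. A cluster of 1206 myeloid cells with APOBEC3A, IFI30 and SERPINA1 had 778 cells labelled pre and 428 labelled post, and 328 and 428 without the library that held 37.3% of it. Another cluster of 38 cells had KIT, TRDC, TNFRSF18 and IL1R1 among its most enriched genes. Unnamed cells made up 17.3% ± 8.95 (SD, n = 7) of libraries labelled pre and 12.1% ± 4.71 (SD, n = 7) of those labelled post, higher in 2 of 7 donors (exact sign-flip permutation test, p = 0.156), and 2341 of them were in a cluster with a median depth of 626 UMIs.

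Among CD4 T-like cells the cluster with CCR7, FHIT and TCF7, genes of naive cells, held 18.2% of the cells labelled pre and 10.9% of those labelled post, and the cluster with IL7R, AQP3 and CCR6, genes of memory cells, held 20.5% and 27.3%. Leaving out each library in turn, the difference ranged from -10.3 to -4.96 percentage points for the first and from 4.14 to 10.9 for the second. The 2 other clusters with CCR7 and LEF1 held 17.3% and 14.5% of the cells labelled pre and 15.01% and 14.3% of those labelled post, with ranges of -3.82 to -0.789 and of -1.78 to 5.05 points. In classical monocyte-like cells the cluster led by S100A8 and VCAN held 55.0% and 41.5%, the cluster with CXCL8 34.0% and 39.3%, and the shallow cluster led by TNFAIP2 and CD36 10.9% and 19.2%. Each of these 3 turned direction without single libraries, with ranges of -24.1 to 20.3, -15.7 to 18.4 and -4.67 to 17.3 points. These shares are pooled over donors and were not tested.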
